A study of Homo sapiens with 12 samples.

How the data were processed

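Messenger RNA levels were measured by RNA sequencing in 12 libraries of human castration-resistant prostate cancer cells, in 6 groups of 2 libraries. The cells were LNCaP-abl, an androgen receptor-positive line derived from LNCaP, and DU145, an androgen receptor-negative line. Each line was treated for 60 to 72 h with the vehicle DMSO or with 5 µM of an inhibitor of EZH2, the methyltransferase of Polycomb repressive complex 2 (PRC2). The inhibitors were EPZ-6438 (tazemetostat) and GSK126. Libraries were made from total RNA with an Illumina TruSeq kit, per the labels' protocols. The labels number the libraries of a group without saying whether they came from separate cultures, so the p-values of single genes measure the spread between these libraries, which may be technical. The p-values of gene lists and of overlaps take genes as units and do not measure a spread between libraries.

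The 4 tables used here hold the authors' own comparisons of each inhibitor with DMSO in each line, and no values per library. Reads were aligned with TopHat2 2.0.6 to hg19 and compared with DESeq2 by the authors, per the submitters' processing notes, which give no DESeq2 version. The read counter, the annotation and the use of strand are not given in the sources used here. Each table lists 23159 gene symbols in 6 columns of values. The mean normalized count over the 4 libraries compared is a signal on the scale of size-factor-normalized reads, per the file headers as deposited. The fold change and its standard error (SE) are log2 values, per the file headers as deposited. The Wald statistic is a score equal to the log2 fold change divided by its SE in every deposited table. The p-value and the adjusted p-value are as deposited, and the authors' adjusted p is missing for genes under a mean count chosen separately for each table. The direction of the fold change is not stated in the headers and was read as inhibitor over DMSO, so the opposite reading would turn every sign.

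The deposited log2 fold changes were shrunken toward 0 by the authors. The SE fell again at low mean counts, with a median of 0.140 below a mean count of 1 and 0.414 at means of 100 to 300 in the LNCaP-abl EPZ-6438 table, as a normal prior centred on 0 gives. The largest SE gives prior standard deviations of 0.853 and 0.761 for EPZ-6438 and GSK126 in LNCaP-abl and of 0.803 and 0.576 in DU145. Fold changes of different tables are therefore on slightly different scales, with DU145 GSK126 shrunken most, and all understate the change of genes with few reads. Statistics and p-values are the authors' own.

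Depth was read from the mean counts of rare genes. Steps of single reads explained 100% of the mean counts below 3 within a tolerance of 1e-06, which gave the scaling factors of the 4 libraries of each table. The factors were not assigned to libraries or groups, so a difference in depth between treated and DMSO libraries was neither tested nor excluded. In LNCaP-abl the factors ranged 1.71-fold in the EPZ-6438 table and 1.52-fold in the GSK126 table. In DU145 they ranged 5.41-fold and 3.01-fold, and the shallowest library of the DU145 EPZ-6438 table held about 3.44 M counted reads against 18.6 M for the deepest. Mean normalized totals were 18.1 and 19.1 M for the LNCaP-abl tables and 9.66 and 16.6 M for the DU145 tables.

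Before the data were examined, a quasi-likelihood count test of all libraries, 25 gene lists and the rule for named genes had been fixed. The planned edgeR tests could not be run, because the tables hold no counts per library. Every test below was therefore chosen after the tables were seen. Genes were called at a deposited adjusted p under 0.05. The difference between the inhibitors within a line, or between the lines for an inhibitor, was a 2-sided z-test of the difference of the deposited log2 fold changes with their SEs taken as independent, with Benjamini-Hochberg adjustment over genes with an adjusted p in both tables. Intervals are 95% intervals from the same SEs. The comparison of the lines in DMSO was not analysed here, since each table pools treated and DMSO libraries in its mean counts.

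Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3. The test sets the mean Wald statistic of a list against that of the other genes with a mean count of 10 or more, with a preset inter-gene correlation of 0.01, and was adjusted by Benjamini-Hochberg over the lists of a comparison. A list needed 3 measured members. An estimated correlation needs values per library and could not be had, so a preset correlation of 0.05 was the stricter alternative. The size of a list's change is the mean log2 fold change of its members minus that of the other genes, with a 95% interval at the same preset correlation. Overlaps of calls were set beside n1 × n2 / N and tested with Fisher's exact test. For inhibitors compared with the same DMSO libraries, 100 simulations of unchanged genes gave the correlation and covariance that shared controls alone produce. The simulations took DMSO and treated groups as equally variable.

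GC content and length of transcripts came from GENCODE release 29 by gene symbol, with no coordinates taken from it, and 22014 of the 23159 symbols (95.1%) had a value. As an alternative, a natural spline with 4 degrees of freedom each on GC content, log2 length and log2 mean count was removed from the Wald statistics. Other alternatives were adjustment over all genes with a p-value, over genes with a mean count of 10 or more or of 100 or more, statistics recentred and divided by their robust spread, lists over other count minimums or on ranks, repair lists without cell cycle genes, fold changes with the shrinkage undone, and SEs of the inhibitor comparisons correlated at 0.5.

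The named genes were EZH2, EZH1, EED and SUZ12 in every table, the 6 called genes with the highest and the 6 with the lowest log2 fold change at a mean of 1 CPM (counts scaled to a common table total) or more, and the 4 members of each list with the lowest p-value. For the differences between the inhibitors and between the lines, the rule also named up to 4 called genes with the largest difference in each direction. The part of the rule that asked both treated libraries to lie beyond both DMSO libraries could not be applied. The steps were tested on simulated data. The list step used the genes of the DU145 EPZ-6438 table with random statistics, independent between genes, and the step for differences used the SEs of that table. Over 13367 genes, 2.5% of lists with no effect passed an unadjusted p of 0.05 by camera, and a shift of the S phase list by 1 unit was called in 20 of 20 runs. With independent genes, that rate cannot show how often lists of genes that move together pass. Over 9071 genes, the test of differences recovered 17% of 2-fold and 77% of 4-fold differences and called 0.0789% of unchanged genes.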

Results

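The response of 2 castration-resistant prostate cancer lines to 2 EZH2 inhibitors was compared at the level of messenger RNA. The labels describe LNCaP-abl cells as sensitive to EZH2 inhibition and DU145 cells as insensitive. Each line had 2 libraries with DMSO, 2 with 5 µM EPZ-6438 and 2 with 5 µM GSK126, after 60 to 72 h. The 4 tables compared each inhibitor with DMSO in each line, and approximate depths ran from 12.8 to 21.8 M counted reads in the LNCaP-abl EPZ-6438 table and from 3.44 to 18.6 M in the DU145 EPZ-6438 table. Fold changes and their SEs are the authors' shrunken log2 values, so where a spread is given beside a gene it is an SE rather than values of single libraries.

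The lines differed in their lineage genes. AR, the androgen receptor, had a mean normalized count of 8960 in LNCaP-abl and 33.7 in DU145 in the authors' deposited table for EPZ-6438. FOLH1, which encodes prostate-specific membrane antigen, had 8504 against 67.7 and ACPP, prostatic acid phosphatase, 2280 against 3.16 in the authors' deposited table of each line. AXL, a receptor tyrosine kinase, was listed at 0 in LNCaP-abl and at 4060 in DU145 in the authors' deposited table. KLK3, which encodes prostate-specific antigen, ran the other way, with 16.6 in LNCaP-abl and 216 in DU145 in the authors' deposited table. These means pool DMSO and treated libraries of tables scaled separately, so the differences have no test.

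In LNCaP-abl cells, genes of DNA replication and mitosis were lower with EPZ-6438 than with DMSO. PLK1, a mitotic kinase, fell by 1.63 on the log2 scale (SE 0.27, adjusted p = 1.57e-05) and MCM5, a subunit of the replicative helicase, fell by 1.57 (SE 0.34, adjusted p = 0.00378) in the authors' deposited table. C19orf48, HIST1H2AD, HIST1H3D and ALYREF, an mRNA export factor, had log2 fold changes of -1.72, -1.70, -1.55 and -1.50 in the authors' deposited table. The largest rises at a mean of 1 CPM or more were those of the long noncoding RNAs KCNQ1OT1 at 1.49 and MALAT1 at 1.42, and of the chromatin genes CHD7 at 1.47 and ARID4B at 1.40, with ZBTB20 at 1.35 and MTRNR2L3 at 1.31 in the authors' deposited table. HIST1H2AD and HIST1H3D are neighbouring histone genes and MTRNR2L3 resembles mitochondrial ribosomal RNA, so their values are uncertain where reads were shared. The authors' deposited table called 57 genes, 19 higher and 38 lower, and 1231 genes had an unadjusted p under 0.05. Adjustment over every gene with a p-value gave 18 calls, over mean counts of 10 or more 28, and over mean counts of 100 or more 30. With the trend on GC content, length and expression removed, 13 genes were called, 7 higher (53.8%) and 6 lower against 33.3% higher as deposited, and 11 of them were among the 57. With the statistics recentred and rescaled, 1 gene was called, and it was lower.

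Of the 54 measured G2 and M phase genes, 48 were lower after EPZ-6438 in LNCaP-abl cells, and the list fell by 0.45 log2 against other genes (95% interval -0.59 to -0.32, camera adjusted p = 2.8e-11). BIRC5, the survivin gene, at -1.33 and RANGAP1 at -1.18 passed the test over all genes in the authors' deposited table, and 5 members were lower when adjusted over the list alone. Of the 42 S phase genes, 36 were lower, and the list fell by 0.48 (-0.63 to -0.34, adjusted p = 1.23e-10). MCM5, TYMS (thymidylate synthase) at -1.15 and MCM2 at -1.08 passed over all genes in the authors' deposited table, and 11 members adjusted over the list alone. The preset correlation of 0.05 left both lists past the threshold at adjusted p = 4.86e-05.

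Lists of DNA repair genes were lower in the same LNCaP-abl comparison. Base excision repair genes fell by 0.48 (25 measured, 23 lower, -0.66 to -0.30, adjusted p = 1e-06), with FEN1, the flap endonuclease, at 0.499 of its DMSO level and the glycosylase NTHL1 at -1.09 log2 as members that did not pass over all genes in the authors' deposited table (adjusted p = 0.0688 and 0.0915). Mismatch repair genes fell by 0.31 (21 measured, adjusted p = 0.00491), and genes of homologous recombination and the Fanconi anemia pathway fell by 0.24 (42 measured, adjusted p = 0.0107). No member of the 3 lists passed over all genes by the authors' DESeq2 test; adjusted over the list alone, 4, 2 and 0 members were lower, and 7, 3 and 7 were lower at an unadjusted p under 0.05. The lists share 3, 6 and 3 genes with the cell cycle lists, and without these the adjusted p was 7.93e-05, 0.0308 and 0.0309 in the same order. The base excision and mismatch repair lists also share genes, and LIG1 and POLD1 stayed in both. Only members of the cell cycle lists were removed, so a fall of repair genes apart from that of replication genes is not shown. With a correlation of 0.05 the mismatch repair and homologous recombination lists were lost (adjusted p = 0.0656 and 0.164).

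Stress and sterol genes were also lower with EPZ-6438 in LNCaP-abl cells. The integrated stress and unfolded protein response list fell by 0.26 (31 measured, 23 lower, adjusted p = 0.00479), with the pseudokinase gene TRIB3 at -1.01 and the amino acid transporter subunit SLC3A2 at -0.96, neither past the threshold in the authors' deposited table. Cholesterol synthesis genes fell by 0.19 (25 measured, adjusted p = 0.0455), with TM7SF2, a sterol reductase, at -0.79 and not called in the authors' deposited table. By the authors' DESeq2 test 0 members of either list passed over all genes; adjusted over the list alone 2 and 1 were lower, and 3 and 6 at an unadjusted p under 0.05. Both were lost with a correlation of 0.05 (adjusted p = 0.0746 and 0.216), and the cholesterol list on ranks (0.106) and with the trend removed (0.146).

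The list of genes described as repressed by EZH2 did not pass in LNCaP-abl cells with EPZ-6438 (21 measured, mean difference 0.15, -0.04 to 0.33, adjusted p = 0.265). Its first gene by p-value, IGFBP3, an insulin-like growth factor binding protein, had 0.85 (SE 0.25, adjusted p = 0.057) in the authors' deposited table, and 0 members were called over all genes, 1 when adjusted over the list alone and 1 at an unadjusted p under 0.05 by DESeq2. HOX genes (adjusted p = 0.335), developmental transcription factors bound by Polycomb (0.48) and PRC2 subunits (0.809) did not pass either. EZH2 itself had 0.14 (SE 0.35), EZH1 -0.29, EED -0.30 and SUZ12 -0.39 in the authors' deposited table, where SUZ12 was not called and the other 3 had no adjusted p. VIM, the vimentin gene, had 1.53 (SE 0.38) without an adjusted p in the authors' deposited table. The developmental transcription factors passed, higher, once the trend was removed (adjusted p = 0.0316).

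The remaining lists did not pass in this comparison, with camera adjusted p = 0.24 for LNCaP lineage markers (0.0351, higher, with the trend removed), 0.264 for androgen receptor targets and 0.265 for growth arrest and apoptosis genes. TRPS1, a transcription factor of the LNCaP lineage list, rose by 1.12 (adjusted p = 0.0421), and AR had 0.71 (adjusted p = 0.213) in the authors' deposited table. The p53 targets (adjusted p = 0.686), interferon response genes (0.726), antigen presentation genes (0.617) and lysosome genes (0.617) did not pass. Nor did epithelial-mesenchymal transition genes and neuroendocrine genes (both adjusted p = 0.809), ribosomal protein genes (0.203), immediate early genes (0.739), DU145 and basal epithelial markers (0.191) or fibroblast markers (0.612). Leukocyte markers had fewer than 3 measured members, and CD68 had 0.26 (adjusted p = 0.811) in the authors' deposited table.

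The same cell cycle lists were lower with GSK126 in LNCaP-abl cells. Both inhibitors were compared with the same DMSO libraries, so lists lower with both are not independent repeats. Of the 54 G2 and M phase genes 51 were lower, and the list fell by 0.43 (-0.53 to -0.32, camera adjusted p = 2.06e-15). Of the 42 S phase genes 36 were lower, and the list fell by 0.35 (-0.46 to -0.24, adjusted p = 4.21e-09). HIST1H2AD at -2.02 (SE 0.37, adjusted p = 0.000418) and HIST1H3D at -1.83 (SE 0.36, adjusted p = 0.00327) were the 2 genes called in the authors' deposited table, both lower, and 348 genes had an unadjusted p under 0.05. BIRC5 at -1.29 and TACC3, a spindle protein gene, at -1.17 did not pass over all genes (both adjusted p = 0.382) in the authors' deposited table. Over all genes 0 members of either cell cycle list were called by DESeq2; adjusted over the list alone 4 G2 and M phase genes and 0 S phase genes were lower, and 11 and 4 at an unadjusted p under 0.05. HIST1H2AD alone was called once the trend was removed (adjusted p = 0.0104, against 0.0502 for HIST1H3D).

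Repair lists were lower with GSK126 in LNCaP-abl cells as well, by 0.31 for base excision repair (adjusted p = 9.59e-05), 0.25 for mismatch repair (adjusted p = 0.00242) and 0.16 for homologous recombination and Fanconi anemia genes (adjusted p = 0.0338). NTHL1 had -0.85 and MLH1, a mismatch repair gene, -0.85 in the authors' deposited table, both uncalled. Lysosome genes were higher by 0.13 (31 measured, 21 higher, adjusted p = 0.0487), with the sialidase gene NEU1 at 0.76 and the sterol carrier NPC2 at 0.64 in the authors' deposited table. No member of these 4 lists was called over all genes by DESeq2 or when adjusted over the list alone, and 1, 2 and 2 repair genes were lower and 2 lysosome genes higher at an unadjusted p under 0.05. With a correlation of 0.05 the homologous recombination and lysosome lists were lost (both adjusted p = 0.282), over mean counts of 100 or more the former (0.0604) and on ranks the latter (0.0993), and without cell cycle genes in the repair lists these were at 0.0513. EZH2 had -0.24, EZH1 -0.15, EED 0.10 and SUZ12 -0.06 with no call in the authors' deposited table, and the other 18 lists did not pass (adjusted p = 0.0645 to 0.909).

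**Figure D1:**
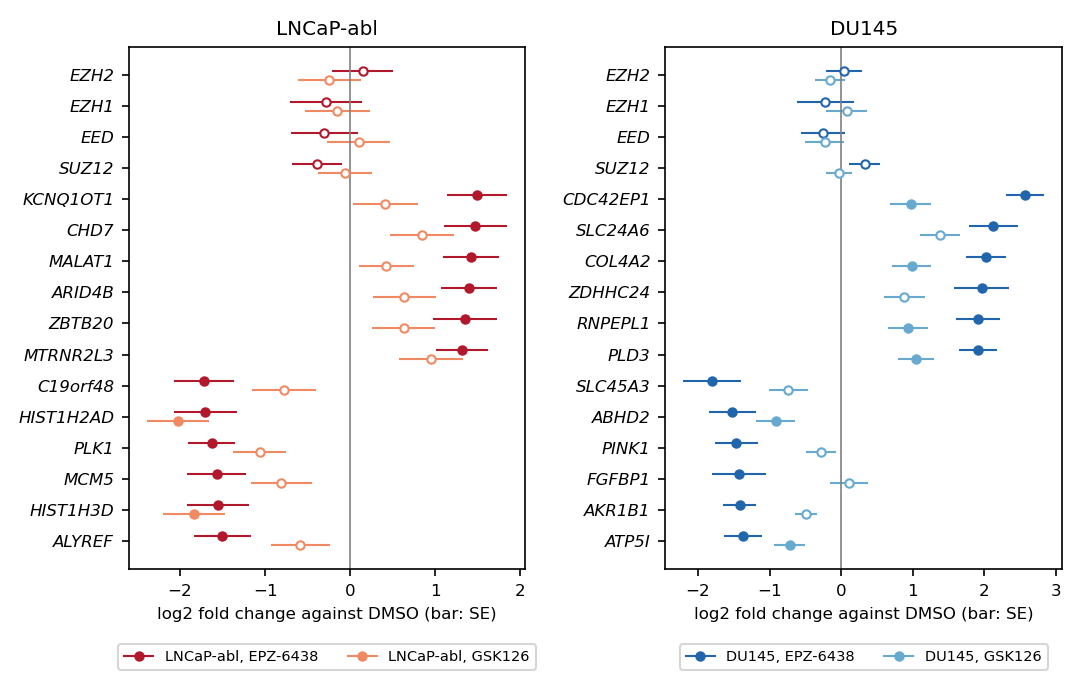
Log2 fold change against DMSO (x axis) of PRC2 genes and of the 6 highest and 6 lowest called genes with EPZ-6438 in LNCaP-abl (left) and DU145 (right). Points are the authors' deposited values for EPZ-6438 (dark) and GSK126 (light), bars are SEs, and filled points have an adjusted p under 0.05; EZH2 lies at 0.14 and -0.24 in LNCaP-abl and at 0.03 and -0.16 in DU145.

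The difference between the inhibitors at the same dose was tested in LNCaP-abl cells. PLK1 was 0.56 higher on the log2 scale with GSK126 than with EPZ-6438 (-0.25 to 1.38), MCM5 0.76 higher (-0.21 to 1.73) and BIRC5 0.04 higher (-0.82 to 0.90), none of them past the threshold (each adjusted p = 1.00). By the z-test 0 of 5596 genes differed, and 8 had an unadjusted p under 0.05. The median 95% interval, not adjusted for the number of genes, reached 0.883 to either side, and in data simulated from a DU145 table the test recovered 17% of 2-fold differences. That simulation had no shared DMSO libraries. The z statistics here had a robust standard deviation of 0.545, below that of a standard normal, so the test was conservative and a count of 0 does not show that the inhibitors act alike. As lists, ribosomal protein genes were higher with GSK126 than with EPZ-6438 by 0.20 (39 of 40 higher, adjusted p = 5.83e-05), lysosome genes by 0.22 (23 of 31, adjusted p = 0.000952) and cholesterol synthesis genes by 0.20 (18 of 25, adjusted p = 0.00712). The G2 and M phase list did not differ detectably (0.02, -0.07 to 0.12, adjusted p = 0.854). The S phase list (0.13, 0.02 to 0.23) and the developmental transcription factors (-0.13, -0.24 to -0.02) missed the threshold (both adjusted p = 0.0733) and passed on ranks (both 0.0425) and with the trend removed (0.0152 and 0.019), the S phase list also with no minimum count (0.0331), where base excision repair genes, higher with GSK126, passed too (0.0487). Leukocyte markers, too few to test at the usual count minimum, also passed with no minimum count. With the trend removed, the ribosomal and cholesterol lists were lost (adjusted p = 0.276 and 0.0577), and with a correlation of 0.05 the lysosome and cholesterol lists were (0.0529 and 0.101).

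The overlap of calls of the inhibitors in LNCaP-abl cells was HIST1H2AD and HIST1H3D, both lower. Independent lists would share 0.0136 genes, a number that does not allow for the shared DMSO libraries. Across 10424 genes, which are not independent replicates, the log2 fold changes had r = 0.746 and a covariance of 0.0996, against 0.497 and 0.0607 simulated for unchanged groups with shared DMSO libraries. The 2 DMSO libraries could not be split, so part of the excess may come from the shared controls.

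In DU145 cells, more genes were called with EPZ-6438 than in LNCaP-abl cells. Depths and the count limits for an adjusted p differed between the tables, so the numbers of calls do not show a larger response. CDC42EP1, a Cdc42 effector gene, rose by 2.57 on the log2 scale (SE 0.26, adjusted p = 2.49e-18) and COL4A2, a basement membrane collagen gene, rose by 2.02 (SE 0.28, adjusted p = 1.9e-09) in the authors' deposited table. SLC24A6 at 2.13, ZDHHC24 at 1.96, RNPEPL1 at 1.91 and PLD3 at 1.91 were the other largest rises in the authors' deposited table. SLC45A3 (prostein) fell by 1.80 (adjusted p = 0.000594), and ABHD2 at -1.52, the mitophagy kinase gene PINK1 at -1.47, FGFBP1 at -1.42, the aldose reductase gene AKR1B1 at -1.42 and ATP5I at -1.37 were the other largest falls in the authors' deposited table. The authors' deposited table called 719 genes, 403 higher (56.1%) and 316 lower, and 2179 had an unadjusted p under 0.05. With the statistics recentred and rescaled 37 were called, 94.6% of them higher, and with the trend removed 368, 60.6% higher.

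Ribosomal protein genes were lower with EPZ-6438 in DU145 cells, by 0.35 (32 of 40 lower, -0.51 to -0.19, camera adjusted p = 1.51e-06). RPL19 at -1.05, RPLP0 at -1.05 and RPL32 at -0.91 fell, while RPS19 rose by 0.65 (adjusted p = 0.0153) in the authors' deposited table. Over all genes 9 members fell and 1 rose, and 14 and 2 when adjusted over the list alone. Cholesterol synthesis genes fell by 0.32 (20 of 25 lower, -0.52 to -0.13, adjusted p = 0.000968), with IDI1 and ACAT2 both at -1.08 and INSIG1, a sterol sensor gene, at -0.87, while SREBF2, the gene of the sterol-responsive transcription factor, rose by 1.31 (adjusted p = 0.000581) in the authors' deposited table. Over all genes 6 of these fell and 1 rose, and 7 and 1 when adjusted over the list alone. With the trend removed the ribosomal list was lost (adjusted p = 0.538) and the cholesterol list was kept (0.000763).

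LNCaP lineage markers were lower with EPZ-6438 in DU145 cells, by 0.53 (14 of 17 lower, camera adjusted p = 0.000448). The source of these markers in an androgen receptor-negative line was not settled, so RNA of other cells was not excluded as a source of the fall. SLC45A3 was the 1 member called over all genes, and 2 were lower when adjusted over the list alone; HOXB13 had -1.44 at a mean count of 48.4, without an adjusted p, and FOXA1 -0.51 in the authors' deposited table. Over genes with a mean count of 100 or more the list was lost (adjusted p = 0.4). Developmental transcription factors bound by Polycomb were higher by 0.24 (38 of 47 higher, 0.09 to 0.39, adjusted p = 0.0306), with FOXC1, a forkhead factor, at 1.07 (adjusted p = 0.00134) as the member called in the authors' deposited table over all genes and also the 1 called when adjusted over the list alone. That list was lost with a correlation of 0.05 (adjusted p = 0.299), with the trend removed (0.538), over mean counts of 100 or more (0.104) and with no minimum count (0.0605).

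Single members of lists that did not pass also changed with EPZ-6438 in DU145 cells. ITGB4, an integrin of basal epithelium, rose 2.83-fold (adjusted p = 9.94e-07), AXL by 0.82 log2 (adjusted p = 0.000558) and HLA-C by 1.18 (adjusted p = 0.000178), while B2M, the other chain of that antigen-presenting complex, fell by 0.63 (adjusted p = 0.038) in the authors' deposited table. PPP1R15A at 1.10 and SESN2 at 1.24, both stress response genes, EGR1 at 1.10 and MYC at 0.70 rose, and CHEK2, a checkpoint kinase gene, fell by 1.19 in the authors' deposited table. MCM2 and MCM5, which fell in LNCaP-abl cells, rose by 0.82 and 0.95 in the authors' deposited table. Among genes described as repressed by EZH2, FOXC1 rose while PEBP1 at -0.85 and CDKN2A at -0.74 fell, and 2 rose and 2 fell over all genes, 4 and 2 when adjusted over the list alone, in the authors' deposited table (camera adjusted p = 0.732). EZH2 had 0.03, EED -0.25 and SUZ12 0.33 with no call, and EZH1 -0.22 without an adjusted p, in the authors' deposited table. The 20 lists that did not pass had adjusted p = 0.0541 to 0.938, with the G2 and M phase genes (-0.18, -0.32 to -0.04) and the immediate early genes (0.20, -0.01 to 0.42) nearest to the threshold. With no minimum count these and the androgen receptor targets, lower, passed (each 0.0339), on ranks the G2 and M phase genes (0.0381), and over mean counts of 100 or more the immediate early genes (0.0232). The DU145 and basal epithelial markers passed, higher, once the trend was removed (adjusted p = 0.0198).

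With GSK126 in DU145 cells, ZNF385A rose by 1.35 (SE 0.22, adjusted p = 3.8e-06), the transcriptional repressor gene CIC by 1.25, ALG3 by 1.21, DPM2 by 1.19, PACS2 by 1.15 and SREBF2 by 1.14 in the authors' deposited table. RSPO1, a Wnt agonist gene, fell by 1.01 (SE 0.24, adjusted p = 0.00555), and ABHD2 at -0.91, ACBD5 at -0.88, the nuclear receptor gene NR4A2 at -0.88, PSMD9 at -0.76 and MALAT1 at -0.76 were the other largest falls in the authors' deposited table. ITGB4 rose by 0.91, AXL by 0.60, HLA-C by 0.74 and EGR1 by 1.01 in the authors' deposited table, all of them called with EPZ-6438 as well. The authors' deposited table called 198 genes, 148 higher (74.7%) and 50 lower, and 1607 had an unadjusted p under 0.05. With the trend removed 68 were called, 88.2% higher, and with the statistics recentred and rescaled 15 were called, 100% higher. EZH2 had -0.16, EED -0.23 and SUZ12 -0.03 with no call, and EZH1 0.08 without an adjusted p, in the authors' deposited table.

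Cholesterol synthesis genes were higher with GSK126 in DU145 cells, by 0.23 (19 of 25 higher, 0.11 to 0.36, camera adjusted p = 0.000422). DHCR7, which makes cholesterol in its last step, rose by 1.03 (adjusted p = 4.45e-06) and FDPS, farnesyl diphosphate synthase, by 0.71 (adjusted p = 0.00306) in the authors' deposited table; with SREBF2, 3 members rose over all genes and 5 when adjusted over the list alone. Interferon response genes were higher by 0.21 (27 of 38 higher, 0.11 to 0.32, adjusted p = 0.000422), with IRF9 at 0.81, OASL at 0.63 and ISG15 at 0.47 in the authors' deposited table. G2 and M phase genes were lower by 0.20 (42 of 54 lower, -0.29 to -0.11, adjusted p = 0.000422), with CDK1 at -0.63 and ANP32E at -0.55 in the authors' deposited table. Of these last lists 0 members passed over all genes by DESeq2 or when adjusted over the list alone, and 9 interferon genes were higher and 12 G2 and M phase genes lower at an unadjusted p under 0.05. These 3 lists stayed past the threshold with a correlation of 0.05 (each adjusted p = 0.0446) and with the trend removed.

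Weaker list changes with GSK126 in DU145 cells were lower ribosomal protein genes (-0.13, adjusted p = 0.0138), lower LNCaP lineage markers (-0.19, adjusted p = 0.0265), higher developmental transcription factors bound by Polycomb (0.13, adjusted p = 0.0443) and higher immediate early genes (0.14, adjusted p = 0.0481). RPS19 rose by 0.85 (adjusted p = 0.00257), against the direction of its list, and was the 1 ribosomal member called over all genes and adjusted over the list alone in the authors' deposited table. EGR1 and JUND, at 0.71, were the 2 immediate early genes called over all genes in the authors' deposited table, with 3 adjusted over the list alone, while the median of that list was 0.02. No LNCaP marker or developmental factor was called over all genes by DESeq2 or adjusted over the list alone, and at an unadjusted p under 0.05 there were 3 lower and 1 higher markers and 6 higher factors. With a correlation of 0.05 all 4 lists were lost (adjusted p = 0.174, 0.164, 0.293 and 0.211), and with the trend removed the ribosomal list turned to higher without passing (0.377) and the developmental factors and immediate early genes were lost (0.877 and 0.198). The LNCaP markers were lost over mean counts of 100 or more (0.159), the developmental factors with no minimum count (0.167) and the immediate early genes on ranks (0.239). The other 17 lists had adjusted p = 0.0627 to 0.994. Under removal of the trend the DU145 and basal epithelial markers passed, higher (0.0412), and with no minimum count the androgen receptor targets, lower (0.0254).

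**Figure D2:**
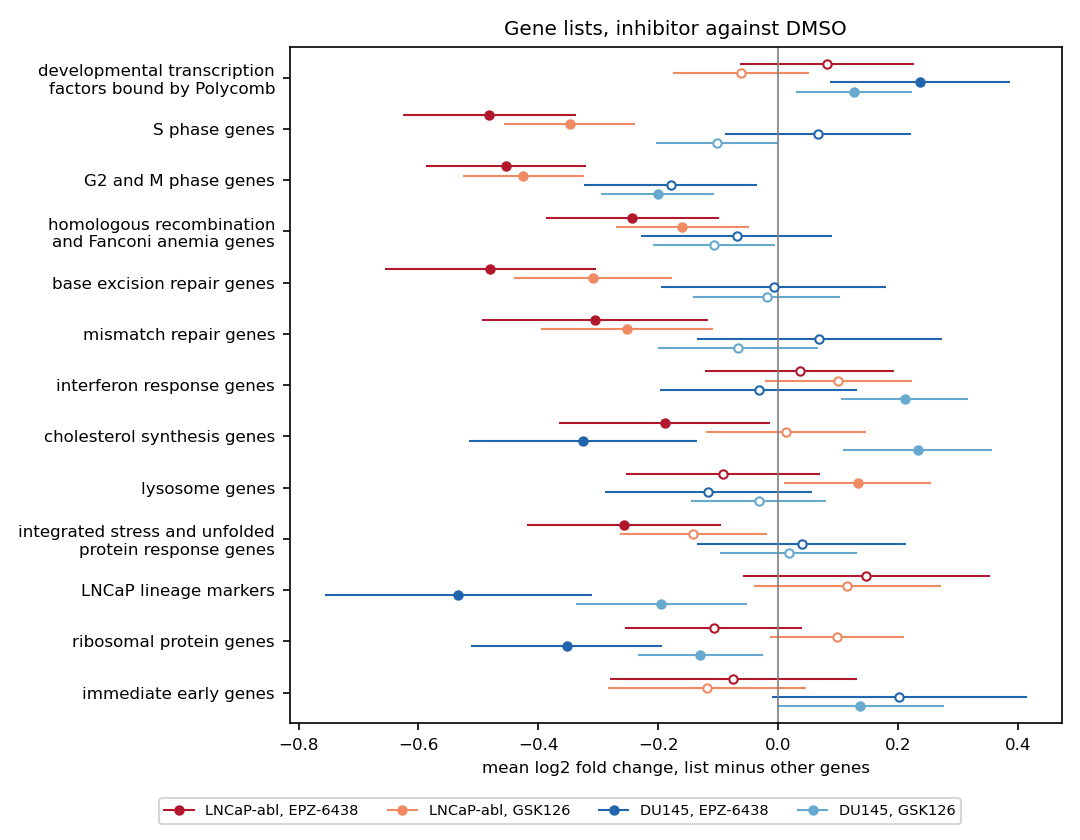
Mean log2 fold change of each gene list minus that of the other genes (x axis) in the 4 comparisons with DMSO, for lists past an adjusted p of 0.05 in any of them. Bars are 95% intervals and filled points have an adjusted p under 0.05; the S phase list lies at -0.48 and -0.35 in LNCaP-abl, and the cholesterol list at -0.32 with EPZ-6438 and 0.23 with GSK126 in DU145.

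The inhibitors differed in DU145 cells for sterol and interferon genes. Cholesterol synthesis genes were higher with GSK126 than with EPZ-6438 by 0.56 (24 of 25 higher, 0.43 to 0.69, camera adjusted p = 3.49e-21), with FDPS 0.89 higher (0.35 to 1.42), INSIG1 0.80 higher (0.25 to 1.35) and DHCR7 0.65 higher (0.09 to 1.20). Interferon response genes were higher by 0.25 (28 of 37, adjusted p = 1.44e-05), ribosomal protein genes by 0.22 (34 of 40, adjusted p = 8.5e-07) and LNCaP lineage markers by 0.32 (16 of 17, adjusted p = 0.000155), and S phase genes were lower by 0.17 (34 of 43, adjusted p = 0.00715). The ribosomal and LNCaP marker lists were lower with both inhibitors, by 0.35 and 0.53 with EPZ-6438 and by 0.13 and 0.19 with GSK126. The GSK126 fold changes were shrunken more, and no list was tested with the shrinkage undone. A difference of scale was therefore not excluded as a source of the differences of these lists. The G2 and M phase list did not differ detectably (-0.02, -0.12 to 0.08, adjusted p = 0.686). Gene by gene 0 of 7437 passed the z-test, 155 had an unadjusted p under 0.05, and CDC42EP1 came nearest (-1.60, -2.37 to -0.84, adjusted p = 0.15). The z statistics had a robust standard deviation of 0.774, so the test was conservative here too. Shared DMSO libraries of like depth would give errors correlated at 0.5. Depths ranged 5.41-fold and 3.01-fold in the DU145 tables, so the true correlation is unknown. Taken at 0.5 in the z-test, 22 genes differed, 18 higher and 4 lower with GSK126. Among them were CDC42EP1, FASN (fatty acid synthase, 0.99 higher, adjusted p = 2.3e-05), FDPS, INSIG1 and IDI1. With the trend removed the ribosomal list was lost (adjusted p = 0.156), with a correlation of 0.05 the S phase list (0.151), and over genes with a mean count of 100 or more the LNCaP markers (0.275).

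Calls shared by both inhibitors in DU145 cells were 113 higher and 36 lower genes, among them CDC42EP1, SREBF2 and ABHD2. Most of these shared calls were lost with the trend removed, and more with the statistics recentred and rescaled. Independent lists would share 6.19 and 2.08, which does not allow for the shared DMSO libraries. Across 9069 genes the log2 fold changes had r = 0.770 and a covariance of 0.103, against 0.50 and 0.0320 simulated for unchanged groups with shared DMSO libraries. As in LNCaP-abl cells, part of the excess may come from the shared controls, which could not be split. The simulated values also assume groups of like variance, which the unequal depths of the DU145 libraries leave uncertain.

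The effect of EPZ-6438 differed between the lines for 408 of 5254 genes by the z-test, 95 with the higher fold change in LNCaP-abl and 313 with the lower. CDT1, a replication licensing factor, had -1.46 in LNCaP-abl and 1.51 in DU145 in the authors' deposited table, a difference of -2.98 (-3.79 to -2.16, adjusted p = 3.8e-09). RNPEPL1, HIST2H2BA and AGRN followed with differences of -2.74, -2.55 and -2.54. MALAT1 differed by 1.99 (1.24 to 2.74, adjusted p = 5.43e-05), with 1.42 in LNCaP-abl and -0.57 in DU145 in the authors' deposited table, and ID2, AQP3 and MPP1 differed by 1.84, 1.82 and 1.78. The S phase list was lower in LNCaP-abl relative to DU145 by 0.54 (-0.77 to -0.30, camera adjusted p = 6.92e-05) and the G2 and M phase list by 0.27 (-0.49 to -0.06, adjusted p = 0.031). LNCaP lineage markers had the higher change in LNCaP-abl, by 0.64 (adjusted p = 0.00464), and androgen receptor targets by 0.36 (adjusted p = 0.031). These lists share members, among them KLK3, NKX3-1 and SLC45A3, so they are not separate results. Base excision repair genes (-0.49, adjusted p = 0.00995), mismatch repair genes (-0.37, adjusted p = 0.0332) and stress response genes (-0.30, adjusted p = 0.031) had the lower change in LNCaP-abl, and ribosomal protein genes the higher (0.25, adjusted p = 0.031). Removal of the trend left 132 genes, the ribosomal list was lost (adjusted p = 0.732), and genes described as repressed by EZH2 (higher in LNCaP-abl) and homologous recombination genes (lower) passed (both 0.0318); with the statistics recentred and rescaled 15 genes differed, and without cell cycle genes the mismatch repair list was lost (0.0752). With a correlation of 0.05 the S phase and LNCaP marker lists were kept (adjusted p = 0.0341 and 0.0432), and the other 6 were lost, base excision repair at 0.12, the G2 and M phase list at 0.231 and the rest at 0.211. Over genes with a mean count of 100 or more the S phase list was kept (adjusted p = 0.000473) and the other 7 were lost (0.109 to 0.313), LNCaP markers at 0.244.

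The effect of GSK126 differed between the lines for 10 of 7207 genes by the z-test. Fewer differed over mean counts of 100 or more and with the shrinkage undone. CDT1 had -1.18 in LNCaP-abl and 1.12 in DU145 in the authors' deposited table, a difference of -2.29 (-3.09 to -1.50, adjusted p = 0.000104). ALG3, RMRP, ZNF787 and ZNF385A had differences of -1.89, -1.79, -1.74 and -1.65, and SAT1 and NR4A2 of 1.68 and 1.54. The S phase list was lower in LNCaP-abl relative to DU145 by 0.26 (adjusted p = 0.0286), the G2 and M phase list by 0.23 (adjusted p = 0.0325), base excision repair genes by 0.29 (adjusted p = 0.0402) and immediate early genes by 0.29 (adjusted p = 0.0478), and ribosomal protein genes were higher by 0.22 (adjusted p = 0.0286). Each of these lists was lost with a correlation of 0.05 (adjusted p = 0.219 to 0.245), and without cell cycle genes in the repair lists base excision repair and immediate early genes were lost (both 0.0592). Removal of the trend left 3 genes, and the ribosomal, base excision repair and immediate early lists were lost (adjusted p = 0.652, 0.1 and 0.316), while mismatch repair (0.03, lower), cholesterol synthesis and stress response genes (both 0.0349, lower) and LNCaP markers (0.0209, higher) passed. Over genes with a mean count of 100 or more the S phase list was kept (adjusted p = 0.0423) and the other 4 were lost (0.0519 to 0.089). With no minimum count LNCaP markers, higher, passed (0.0294). Against DMSO, the G2 and M phase list was at -0.43 in LNCaP-abl and -0.20 in DU145, and the S phase list at -0.35 and -0.10. The DU145 fold changes for GSK126 were shrunken more, and no list was tested with the shrinkage undone. A difference of scale was therefore not excluded as part of the differences of the cell cycle lists.

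Of the 38 genes called lower with EPZ-6438 in LNCaP-abl cells, 32 had a positive fold change in DU145. The 19 called higher had 8 above and 11 below 0 in DU145. Of the genes called with EPZ-6438 in DU145, 323 of 399 higher ones were below 0 in LNCaP-abl. The 310 lower ones had 158 above and 152 below 0. Of those called lower in LNCaP-abl, 9 of the 30 tested in both lines were called higher in DU145. Independent lists would share 1.26 (Fisher's exact test, p = 2.23e-06). That number was 4 with adjustment over every gene with a p-value or over mean counts of 10 or more, 5 over mean counts of 100 or more, 1 with the trend removed and 0 with the statistics recentred and rescaled, where 1 gene was called in LNCaP-abl. No gene was called lower in both lines (independent lists, 1.38), and 1 was called higher in both (0.628). Across 8229 genes the fold changes of the lines for EPZ-6438 had r = -0.230, and across 9055 genes those for GSK126 had r = -0.276. Fold changes ran with GC content, downward in LNCaP-abl and upward in DU145: Spearman's rho of the Wald statistic with GC content across genes was -0.439 and -0.324 for EPZ-6438 and GSK126 in LNCaP-abl, and 0.244 and 0.397 in DU145. The median GC content of genes called higher was 40.8% with EPZ-6438 in LNCaP-abl and 61.1% in DU145.

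**Figure D3:**
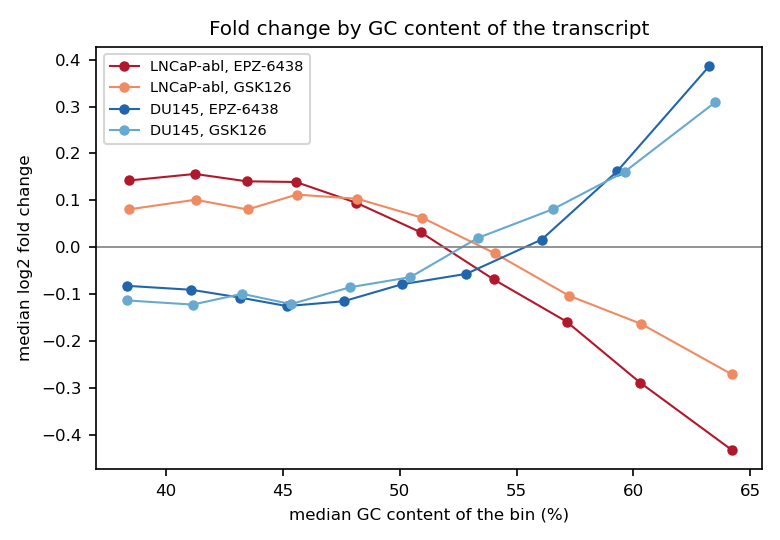
Median log2 fold change against DMSO (y axis) in 10 bins of transcripts by GC content (x axis, median of the bin in percent), for genes with a mean count of 100 or more. In the highest bin the median is -0.43 with EPZ-6438 and -0.27 with GSK126 in LNCaP-abl, and 0.39 and 0.31 in DU145.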

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

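Only the test of GC content, length and expression against the cell cycle lists and against the opposite signs of the lines for EPZ-6438 was fixed ahead of its result; the same test for GSK126, the tests of batches and of other RNA, and the tests of the differences between lines, were chosen after the results were seen. The results of this part drew attention because the effect of an inhibitor differed between the lines when the difference itself was tested. For EPZ-6438 408 genes differed and for GSK126 10. Most of the 408 were lost with the trend removed, and more with the statistics recentred and rescaled. Most of the 10 were lost with the trend removed.

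Of the 408, named genes with the lower fold change in LNCaP-abl for EPZ-6438 were CDT1 (-2.98), RNPEPL1 (-2.74), HIST2H2BA (-2.55), AGRN (-2.54), MCM5 (-2.52), C19orf48 (-2.43), PLD3 (-2.14), ITGB4 (-2.09), CTSD (-1.98), SREBF2 (-1.90), MCM2 (-1.90), RANGAP1 (-1.88), NTHL1 (-1.61) and IER2 (-1.60). Others were ALYREF (-1.55), TRIB3 (-1.53), POLD2 (-1.37), MPG (-1.33), TYMS (-1.30), HLA-C (-1.29), BIRC5 (-1.26), TAPBP (-1.235), MYC (-1.15) and SLC7A5 (-1.13). Among the named genes, those with the higher fold change were MALAT1 (1.99), ID2 (1.84), AQP3 (1.82), MPP1 (1.78), PINK1 (1.77), ATP5I (1.67), BTG1 (1.51), ARID4B (1.47), RPL19 (1.38), ABHD2 (1.27), INSIG1 (1.16), LIPA (1.15), BCL2L11 (1.14) and RPL32 (1.08). The lists that differed were the S phase (-0.54), base excision repair (-0.49), mismatch repair (-0.37), stress response (-0.30) and G2 and M phase (-0.27) genes, and, higher in LNCaP-abl, LNCaP markers (0.64), androgen receptor targets (0.36) and ribosomal protein genes (0.25). With a correlation of 0.05 the S phase and LNCaP marker lists were kept (adjusted p = 0.0341 and 0.0432) and the other 6 were lost (0.12 to 0.231); over mean counts of 100 or more the S phase list alone was kept.

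For GSK126 the named genes, 7 of the 10, were CDT1 (-2.29), ALG3 (-1.89), RMRP (-1.79), ZNF787 (-1.74) and ZNF385A (-1.65), with SAT1 (1.68) and NR4A2 (1.54) the other way. The lists were base excision repair (-0.29), immediate early (-0.29), S phase (-0.26) and G2 and M phase (-0.23) genes, and ribosomal protein genes (0.22), and each was lost with a correlation of 0.05 (adjusted p = 0.219 to 0.245). For the S phase and G2 and M phase lists, stronger shrinkage of the DU145 fold changes was not excluded as part of the difference.

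The fall of S phase and G2 and M phase genes with EPZ-6438 in LNCaP-abl cells was weighed first. A trend on GC content, length and expression was excluded as the whole cause, since after its removal the higher camera p of the lists, not adjusted, was 1.2e-17. The median GC content was 44.7% for the S phase and 43.5% for the G2 and M phase list, against 49.4% for genes with a mean count of 100 or more. Genes of such GC content had a median log2 fold change of 0.14, so removal of the GC part was unlikely to end the fall. The list test sets a list against the other genes, so by its construction a shift common to every gene would not give the fall. A batch of culture that followed the treatment cannot be told apart from the inhibitor, because 0 libraries had values of their own. The fall in the line described as sensitive may be a response to the inhibitor, a hypothesis that these tests leave open beside the batch.

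The opposite signs of the lines were weighed next. Across genes the Wald statistics for EPZ-6438 had r = -0.220, and -0.112 (95% interval -0.133 to -0.0908) once the trend on GC content, length and expression was removed from both tables. That left 51.0% of the correlation, and since the interval spans the size of -0.11 set as the bound beforehand, the trend and a difference between the lines cannot be told apart as the main source. For GSK126 r went from -0.273 to -0.126 (-0.147 to -0.106), 46.3% of its size, and the interval again spans the bound, here -0.137. The genes of an interval across genes are not independent, so the true interval is likely wider.

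LNCaP lineage markers in the DU145 tables were weighed last. KLK3 had a mean count of 216 in DU145 against 16.6 in LNCaP-abl, and AR 33.7 against 8960. The ratios of DU145 to LNCaP-abl means ranged 9378-fold over the markers, from ACPP (0.00139) to KLK3 (13.0), the gene that had prompted the test. RNA of LNCaP-abl cells in a DU145 library cannot be the whole source of KLK3 and KLK2 (8.19), which had higher means in DU145. AR, HOXB13 and FOLH1 had ratios of 0.00376, 0.00713 and 0.00796. A small share of LNCaP-abl RNA was not excluded as a source of these. ACPP had a lower ratio, but with a mean count of 3.16 in DU145 it sets no firm limit on that share. RNA of other androgen receptor-positive cells was not tested, and no biological explanation was tested. Whether foreign RNA was spread unevenly over the DU145 libraries could not be tested without values per library. It was therefore not excluded as a source of the changes of the LNCaP marker list in DU145, or of its differences between inhibitors and lines. The androgen receptor targets share members with that list, so the same holds for their difference between the lines for EPZ-6438.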

How the results depend on the processing

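All alternatives reported here were chosen after the tables were seen. No paired analysis was possible because the deposited tables hold no values per library. Library-size and other scalings, count filters, a second count test, left-out libraries, an estimated correlation and the lines in DMSO were planned and not run for the same reason. Of 90 calls of named genes, 70 were kept with adjustment over every gene with a p-value, 54 of 89 with the trend on GC content, length and expression removed and 14 of 90 with the statistics recentred and rescaled. Of 45 lists past the threshold, 20 were kept with a correlation of 0.05, 41 on ranks, 29 over genes with a mean count of 100 or more, 43 with no minimum and 32 with the trend removed. Under that last setting the ribosomal list of DU145 with GSK126 reversed without passing (adjusted p = 0.377, against 0.00516 to 0.174 under its other alternatives), and the cause was not tested.

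Counts of called genes moved as follows. Recentring and rescaling left 1 gene for EPZ-6438 in LNCaP-abl, 37 and 15 for EPZ-6438 and GSK126 in DU145, and 15 for the difference between the lines for EPZ-6438. It gave 1 and 15 differences between the inhibitors in LNCaP-abl and DU145. Recentring and rescaling were not run apart, and the cause was not tested. Overlaps of calls in the same direction became 0 in LNCaP-abl, 11 in DU145 and 0 between the lines for EPZ-6438, and 0 genes were called lower in LNCaP-abl and higher in DU145. Removing the trend left 13, 1, 368 and 68 calls in the tables in the order LNCaP-abl EPZ-6438 and GSK126, DU145 EPZ-6438 and GSK126, differences between the lines of 132 genes for EPZ-6438 and 3 for GSK126, same-direction overlaps of 0, 49 and 0, and 1 gene lower in LNCaP-abl and higher in DU145; the cause was not tested. Adjustment over every gene, over mean counts of 10 or more and of 100 or more gave 18, 28 and 30 calls for EPZ-6438 in LNCaP-abl, where more genes were tested, a same-direction overlap between the lines for EPZ-6438 of 0, 0 and 0, and 4, 4 and 5 genes lower in LNCaP-abl and higher in DU145. Errors correlated at 0.5 gave 22 differences between the inhibitors in DU145, by the smaller SE. For the difference between the lines for GSK126, 6 genes were left over mean counts of 100 or more and 4 with the shrinkage undone; the cause was not tested.

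Counts of lists past the threshold moved as well. With a correlation of 0.05 these were 3 for EPZ-6438 in LNCaP-abl, 3 for GSK126 in DU145, 1 between the inhibitors in LNCaP-abl, and 2 and 0 between the lines for EPZ-6438 and GSK126, by the wider variance. On ranks 5 and with no minimum count 6 lists differed between the inhibitors in LNCaP-abl. Over mean counts of 100 or more 1 and 1 differed between the lines for EPZ-6438 and GSK126, and without cell cycle genes in the repair lists 3 for GSK126; the cause was not tested. The authors gave no adjusted p below a mean count of 556 and 10.7 for EPZ-6438 and GSK126 in LNCaP-abl and of 71.3 and 292 in DU145, limits that did not follow the totals of 18.1, 19.1, 9.66 and 16.6 M. The first left out EZH2, EZH1 and EED. How far depth limits the calls could not be tested without counts per library.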

Other observations

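All tests of this part were chosen after the values were seen. Histone genes with HIST symbols moved in opposite directions in the lines. In LNCaP-abl 42 of 46 were below 0 with EPZ-6438 (median -0.68, camera adjusted p = 7.62e-16) and 43 of 46 with GSK126 (median -0.55, adjusted p = 3.45e-25), with 3 and 2 called lower. In DU145 26 of 32 were above 0 with EPZ-6438 (median 0.49, adjusted p = 8.15e-05, 5 called higher and 2 lower) and 29 of 36 with GSK126 (median 0.22, adjusted p = 0.00175, 0 called higher and 2 lower). With the trend on GC content, length and expression removed the adjusted p was 8.54e-12, 1.02e-21, 5.53e-05 and 0.00578 in that order. Most replication-dependent histone messages lack a poly(A) tail, and neighbouring histone genes can share reads.

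Genes outside the rule for named genes moved apart between the inhibitors in DU145 when errors were taken as correlated at 0.5. That setting assumes libraries of like depth, which the DU145 libraries were not, and no gene passed with independent errors. The fatty acid genes FASN and SCD were 0.99 and 0.78 higher with GSK126 than with EPZ-6438 (adjusted p = 2.3e-05 and 0.00209), and the interferon-induced gene IFI6 was 0.95 higher (adjusted p = 0.00616). LCN2, which encodes lipocalin-2, had 0.95 with GSK126 and 1.85 with EPZ-6438, a difference of -0.90 (adjusted p = 0.0141).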
